A study of Rattus norvegicus with 35 samples.

How the data were processed

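Kidney RNA of 35 rats' samples was sequenced, with 6 libraries for each of female DK, female NK, male DK, male NK and male HK and 5 for female HK. Per the labels' protocols, RNA was extracted with Trizol, messenger RNA was captured with poly-T beads, and libraries were sequenced on Illumina instruments. The protocols describe directional and non-directional libraries and do not state which was made. Per the submitters' processing notes, fastp, HISAT2 2.0.5, StringTie 1.3.3b and featureCounts 1.5.0-p3 were used. The genome build is not given in the sources used here. The labels give the genotype as WT. They do not state that each library came from a separate animal beyond the sample names.

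The authors deposited a single table of FPKM values, with the length of each gene, for 32545 genes, of which 9038 had no read in any library. Each value multiplied by the gene length gave whole reads within 0.01 read for 100% of the values, so reads per gene could be recovered. The library size that makes the reads whole differed from the sum of reads by a factor of 0.813 to 1.1624, so the deposited values include a scaling between libraries by the authors. Recovered reads in genes were 13.99 to 28.66 M per library. At the median of 14.98 M, 3 reads per library were taken as the floor for groups without a read.

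Values were used as deposited, as log2 of FPKM plus 0.5, for the 14264 genes with an FPKM of at least 1 in at least 5 libraries. All 35 libraries were fitted together in limma 3.58.1 with 1 mean for each of the 6 groups, moderated variances with a trend and 29 residual degrees of freedom. The 12 contrasts were DK vs NK, HK vs NK and DK vs HK in each sex, the sex difference in each of these as an interaction, and males against females on each diet. P-values were adjusted by Benjamini-Hochberg over the genes tested, and genes with an adjusted p under 0.05 were called, without a fold minimum. Means and SD are of FPKM, and log2 changes are differences of mean log2 values.

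Gene lists, contrasts, the test, the thresholds, the alternatives and the rule for naming genes were chosen before the data were examined, except where the text says otherwise. There were 29 lists with 589 entries, of which 567 matched a gene of the table by name and 22 matched none. The adrenal and the Y-linked lists had fewer than 5 tested members and were not tested; the other 27 were tested with fry, adjusted over the lists of a contrast. Fry asks whether the members move on balance in a single direction and does not compare them with other genes. Camera with an estimated and with a preset correlation were alternatives. Members were also counted with p-values adjusted over the list alone. Member counts are to be read against the share of all tested genes called. That share was 39.1% in female and 4.8% in male DK vs NK, and 36.4% and 4.3% in DK vs HK. For the sex differences in DK vs NK and DK vs HK it was 10% and 5.4%. For males against females it was 21% on NK, 34.4% on DK and 9.9% on HK.

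Genes were named by rule: in diet contrasts the 10 largest rises and 10 largest falls among called genes with a symbol and a mean FPKM of at least 2 in the higher group, in interactions and sex contrasts 5 and 5, up to 4 called members per list, and 25 genes of transport and injury in each diet contrast whatever their p. Of these 25, Kcnma1 did not reach the filter. The text names a part of the genes that the rule allows.

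The sample numbers in the labels fall in the 200s for 4 female NK and 5 male DK libraries and in the 300s for the other 26. Their meaning is not stated, and the series was an alternative covariate. The replicate numbers were tested as pairs across groups and did not pair the libraries. Chi-square per gene between the 85 pairs of libraries of the same group was 8.89 to 91.57, so no library was a copy of another of its group. Pairs across groups were not compared in this way. Scores of single libraries were compared by exact permutation of the group labels.

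The fit was tested on simulated data with 100 changed genes for each fold size. In female DK vs NK, male DK vs NK, female HK vs NK and male HK vs NK, 84%, 84%, 82% and 83% of 2-fold changes and 52%, 55%, 53% and 52% of 1.5-fold changes were recovered, with 10, 8, 4 and 5 false calls. Of 100 random lists, 6, 3, 8 and 3 had a fry p under 0.05.

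Results for some single genes are not reported here. Alternatives were a pseudocount of 0.1 or 1, no filter or a stricter one, median-ratio scaling, quantile normalization, a fit of the groups of the contrast alone, weights per library, the replicate number as a block, the number series as a covariate, libraries of the 300s alone, voom on recovered reads, and leaving out each library in turn. Leaving out the 3 libraries of lowest weight together, library sums of reads in place of the authors' scaling, and the 300s with a single male DK library were chosen after seeing the data. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with jsonlite 2.0.0 and data.table (version 1.17.8).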

Results

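Messenger RNA of the kidney cortex was measured by RNA sequencing in male and female rats that ate 1 of 3 diets. The series title places the experiment in a study of potassium supplementation and depletion in salt-sensitive hypertension. Per the series text, all diets held 4% NaCl. They differed in potassium: deficient (DK), normal at 0.36% (NK) or high at 1.41% (HK). The diets began shortly after a blood pressure telemeter was implanted at 8 weeks of age and lasted 5 weeks, after which the cortex of 1 kidney was frozen. There were 35 libraries in 6 groups, with 6 libraries per group except female HK, which had 5. The labels do not name the strain and do not state separate animals beyond the sample names, so the p-values measure the spread between these samples.

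Reads assigned to genes ranged from 13.99 to 28.66 M (mega-reads) per library, with a median of 14.98 M. The deposited values were FPKM, fragments per gene length and library size, for 32545 genes. Of these, 14264 genes with an FPKM of at least 1 in at least 5 libraries were tested. Mitochondrial transcripts held between 9.71% and 12.2% of the reads on average across the groups. The sexes were as labelled: the Y-linked gene Eif2s3y reached 31.3 to 46.9 FPKM across the male libraries and at most 0.113 FPKM in any female library.

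**Figure D1:**
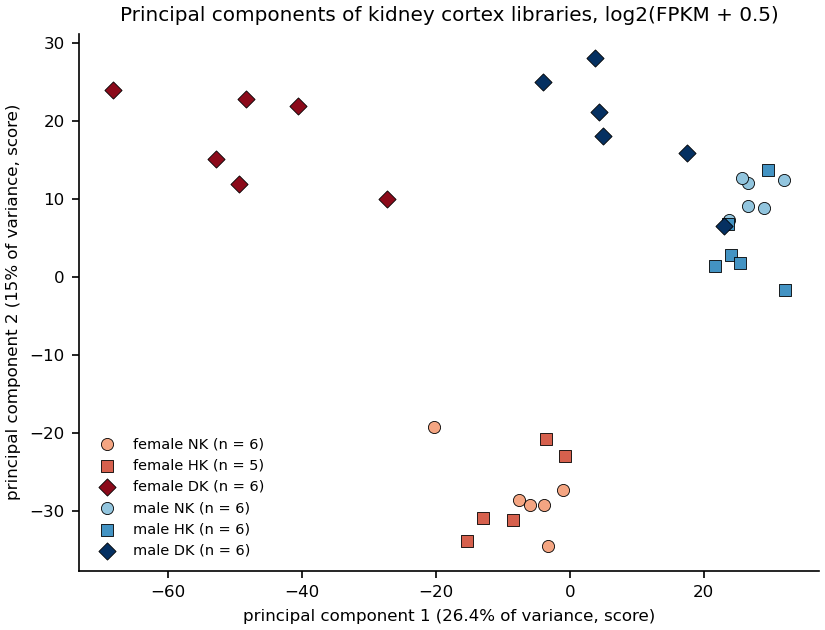
Scores of each library on the leading principal components of the 14264 tested genes, with 26.4% of the variance on the x axis and 15% on the y axis; points are libraries, coloured by group. Female DK libraries lie apart from all other groups, while NK and HK libraries of the same sex share a region.

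**Figure D2:**
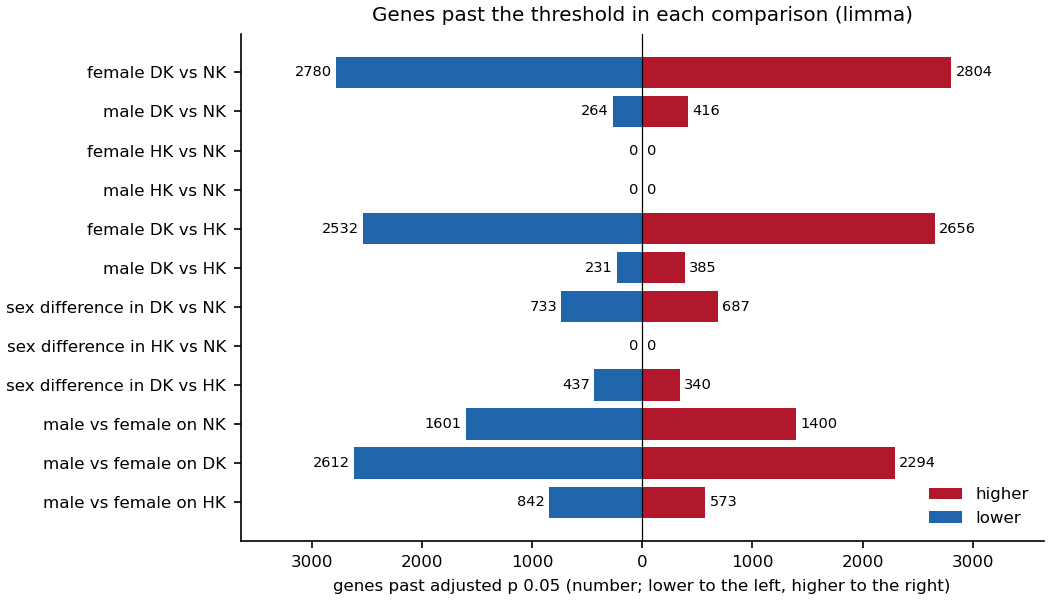
Number of genes past an adjusted p of 0.05 in each comparison, higher to the right and lower to the left. Female DK vs NK has 2804 higher and 2780 lower genes, male DK vs NK 416 and 264, and both HK vs NK comparisons 0.

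In females, potassium deficiency was set against normal potassium to ask what a lack of potassium does to the cortex under high salt. Rbp4, the plasma carrier of retinol, stood at 502.2 ± 241 FPKM in DK (SD, n = 6) and at 7.32 ± 12 in NK, a log2 change of 6.66 (SE 0.60, limma adjusted p = 3.18e-10). The NK mean rests on replicate 4, at 31.82, with the other 5 NK libraries between 1.727 and 3.477. Abcb11, the bile salt export pump, rose from 0.448 ± 0.127 to 55.5 ± 29.9 FPKM. Slc38a3, a glutamine transporter of the proximal tubule, rose from 61.5 ± 21.8 to 974.9 ± 486 FPKM, a log2 change of 3.86 (SE 0.37, adjusted p = 8.32e-10). Tat, which breaks down tyrosine, rose by 4.83 on the log2 scale and Sds, a dehydratase that releases ammonia from serine, by 4.29. Gstm1, a glutathione transferase, rose by 4.82, Fam25a by 5.59, and the tight junction claudins Cldn24, with 6 reads over the 6 NK libraries, and Cldn22 by 3.95 and 3.46. Cyp27b1, the hydroxylase that makes active vitamin D, rose by 3.67.

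The largest falls in female DK included Oacyl, which fell by 4.24 on the log2 scale, from 11.7 ± 4.74 to 0.115 ± 0.0447 FPKM. Gatm, an enzyme of creatine synthesis, fell from 1341 ± 407 to 136 ± 73 FPKM, a log2 change of -3.38 (SE 0.36, limma adjusted p = 9.55e-09). Dio1, a deiodinase of thyroid hormone, fell by 3.25, the hydroxyacid oxidase Hao2 by 2.77 and the retinol dehydrogenase Rdh16 by 2.72. The aldo-keto reductase Akr1b7 fell by 3.52, the homeobox factor Nkx1-2 by 3.13, Fsd1l by 2.87, the monocarboxylate transporter family member Slc16a14 by 2.86 and the crystallin Cryga by 2.82. For each of the 20 genes named as largest, every DK library lay outside the range of the NK libraries. Such separation held for 1663 of the 14264 tested genes, where chance gives 0.216%.

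**Figure D3:**
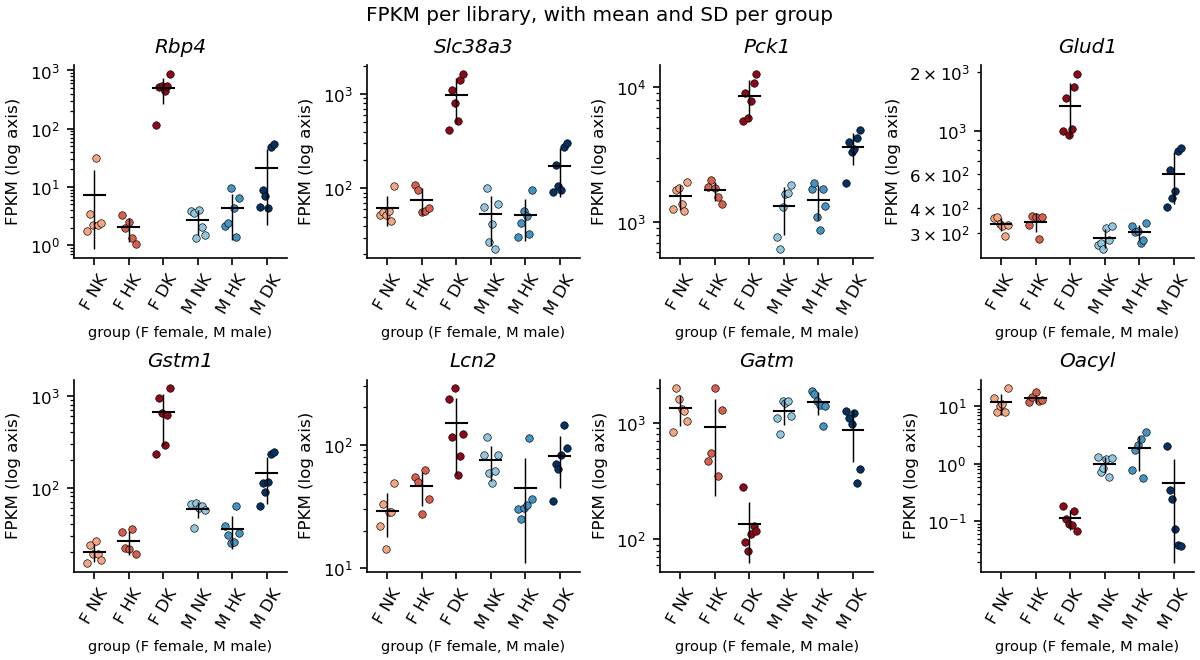
FPKM on a log axis for 8 genes, with each point a library, a horizontal line at the group mean and a vertical line for the SD, which ends near the axis where the mean minus the SD is not above 0. Slc38a3 lies between 412.4 and 1630 FPKM in female DK and at most at 105.2 in female NK.

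Genes of ammonia and acid-base handling rose on balance in female DK by fry. Of the 20 members, 12 rose, 4 fell and 4 did not pass, the same numbers as when adjusted over the list alone (fry adjusted p = 0.000139; adjusted p = 0.623 with an estimated correlation). Pck1, the gluconeogenic carboxykinase, rose from 1554 ± 328 to 8619 ± 2710 FPKM, a log2 change of 2.44. Glud1, which frees ammonium from glutamate, rose by 1.97, the aminotransferase Gpt by 2.15 and the ammonia channel Rhcg by 0.47. Fatty acid oxidation had 21 members up and 1 down of 26, also when adjusted over the list alone (fry adjusted p = 1.11e-05; adjusted p = 0.569 with an estimated correlation). The fatty acid hydroxylase Cyp4a2 was an example, at 2.08. Antioxidant genes had 15 up and 3 down of 25, with the same numbers over the list alone (adjusted p = 8.02e-06; adjusted p = 0.569 with an estimated correlation). Gstm1 led them and Gstp1 rose by 1.92, while Gclc, which starts glutathione synthesis, fell by 2.35. Cholesterol synthesis had 6 up, 3 down and 14 not passed, alike over the list alone, with the reductase Dhcr7 at 2.03. The fry adjusted p of this list was 0.0269, against 0.803 by camera with an estimated correlation and 0.26 with a preset one. Over all tested genes 39.1% were called, near the share of called members in this list.

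Tubular injury genes had 15 members up, 2 down and 7 not passed in female DK, and the numbers adjusted over the list alone were 15 and 2 (fry adjusted p = 0.00308; adjusted p = 0.623 with an estimated correlation). Lcn2, a secreted lipocalin used as an injury marker, rose from 29.2 ± 11.5 to 149 ± 90.6 FPKM, Krt8, a keratin of epithelial cells, by 1.99 on the log2 scale and the stress cytokine Gdf15 by 1.96. Havcr1, the injury marker also called KIM-1, did not pass, at 0.53 (limma adjusted p = 0.343). Thick ascending limb genes had 5 down, 2 up and 4 not passed of 11, the same over the list alone (fry adjusted p = 0.0425; adjusted p = 0.803 with an estimated correlation). The claudins Cldn10 and Cldn16 fell by 1.14 and 1.09.

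The lymphocyte, podocyte, smooth muscle, interferon response and proliferation lists were lower in female DK by fry. Lymphocyte genes had 12 down and 5 not passed of 17, or 13 down and 1 up adjusted over the list alone (fry adjusted p = 8.02e-06; adjusted p = 0.569 with an estimated correlation). The leukocyte phosphatase Ptprc fell by 1.08 and the interleukin receptor chain Il2rb by 0.90. Interferon response genes had 15 down, 3 up and 5 not passed, the same over the list alone (adjusted p = 4.47e-05; adjusted p = 0.569 with an estimated correlation), among them the antiviral GTPase Mx1 at -1.86 and the factor Irf7 at -1.55. Proliferation genes had 18 down and 2 up of 24, or 19 and 2 over the list alone (adjusted p = 4.47e-05; adjusted p = 0.569 with an estimated correlation), with the topoisomerase Top2a at -1.45 and Mki67 at -0.92. Podocyte genes had 8 down and 5 not passed, as over the list alone (adjusted p = 0.00117; adjusted p = 0.623 with an estimated correlation), with Npnt at -1.0 and the podocyte factor Tcf21 at -0.90. Smooth muscle and mesangium genes had 7 down and 6 not passed, as over the list alone (adjusted p = 0.00423; adjusted p = 0.623 with an estimated correlation), with the regulator Rgs5 at -1.24 and the integrin Itga8 at -0.78.

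The other 16 lists did not pass in female DK vs NK. Matrix and fibrosis genes had 13 down and 4 up of 29 (fry adjusted p = 0.0506), with the collagens Col1a1 at -2.10 and Col6a3 at -2.15. Macrophage and myeloid genes had 7 up, 10 down and 8 not passed of 25, with a median log2 change of -0.16, a mean of 0.09 and a downward test direction (adjusted p = 0.73); Gpnmb, of phagocytes, rose by 1.97. Proximal tubule genes had 10 up and 7 down of 23, with a median of 0.32, a mean of -0.06 and an upward direction (adjusted p = 0.671). Circadian clock genes had 4 up and 8 down of 17 (adjusted p = 0.0741), Nr1d1 at -1.76 and Arntl at 1.45. Intercalated cell genes had 6 up and 0 down of 17 (adjusted p = 0.0968), Atp6v0a4 at 0.96. Oxidative phosphorylation had 8 up of 36 (0.0822), endothelium 4 down of 14 (0.0684), potassium transport 5 up and 5 down of 19 (0.132), principal cell and aldosterone response 5 up and 3 down of 17 (0.0968), and distal convoluted tubule 3 up and 2 down of 14 (0.668). The renin-angiotensin list had 4 up and 4 down of 12 (0.775), complement and acute phase 6 up and 4 down of 20 (0.532), immediate early 3 up and 3 down of 17 (0.749), renal medulla 2 up and 2 down of 12 (0.775), adipose 1 up and 1 down of 8 (0.668), and blood 1 up and 0 down of 5 (0.343). Adjusted over the list alone, the counts up and down were 8 and 11 for macrophage, 11 and 8 for proximal tubule, 7 and 0 for oxidative phosphorylation, 0 and 3 for endothelium, 6 and 3 for principal cell, 4 and 5 for renin-angiotensin, 6 and 5 for complement, 1 and 0 for immediate early and 3 and 2 for renal medulla, and as above for the other 7.

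Among 24 transport and injury genes examined whatever their p, 10 rose, 6 fell and 8 did not pass in female DK vs NK. Wnk4, a kinase that regulates the sodium chloride cotransporter, rose by 0.73 on the log2 scale (SE 0.13, limma adjusted p = 2.65e-05), whereas the cotransporter itself, Slc12a3, stood at -0.13 (adjusted p = 0.648). The epithelial sodium channel subunit Scnn1a rose by 0.95 and Scnn1g fell by 0.62. Kcnj10, a basolateral potassium channel, fell by 1.16 (adjusted p = 0.000478). Its partner Kcnj16 stood at 0.01 (adjusted p = 0.978), and at -0.38 (adjusted p = 0.0156) after quantile normalization. Ace rose by 1.46 and the angiotensin receptor Agtr1a fell by 0.64. The kinase Sgk1 rose by 0.91 and Hsd11b2, which inactivates glucocorticoids, fell by 0.47. The secretory potassium channel Kcnj1 at 0.16 and the water channel Aqp2 at -0.16 did not pass. Within the libraries numbered in the 300s, or with the number series as a covariate, the calls of Scnn1g, Kcnj10, Sgk1, Hsd11b2 and Rhcg each ended under at least 1 of these, with adjusted p up to 0.208.

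In all, limma called 5584 genes in female DK vs NK, 2804 higher and 2780 lower, of which 372 and 407 changed more than 2-fold. The labels carry sample numbers in the 200s and 300s, which may mark batches of animals: all female DK and 2 female NK numbers lie in the 300s and 4 female NK numbers in the 200s. Within the 300s alone 3471 genes passed, 3265 of them among the 5584, and with the number series as a covariate 3701 passed, 3544 of them shared; the covariate also ended the calls of the tubular injury (adjusted p = 0.0838), cholesterol synthesis (0.0838) and thick ascending limb (0.137) lists. With library sums in place of the authors' scaling, tried after seeing the data, the median change of all genes went from -0.01 to -0.17, 1447 genes were higher and 4893 lower, the cholesterol synthesis list (adjusted p = 0.706) and the gene Rhcg lost their calls, and the clock (0.000973), endothelium (0.00465), matrix (0.0188) and renin-angiotensin (0.0158) lists passed. With the replicate number as a block thick ascending limb lost its call (0.0638), and the clock (0.0494) and matrix (0.0349) lists passed; matrix also passed after median-ratio scaling (0.0486), and adipose with the number series (0.0422).

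**Figure D4:**
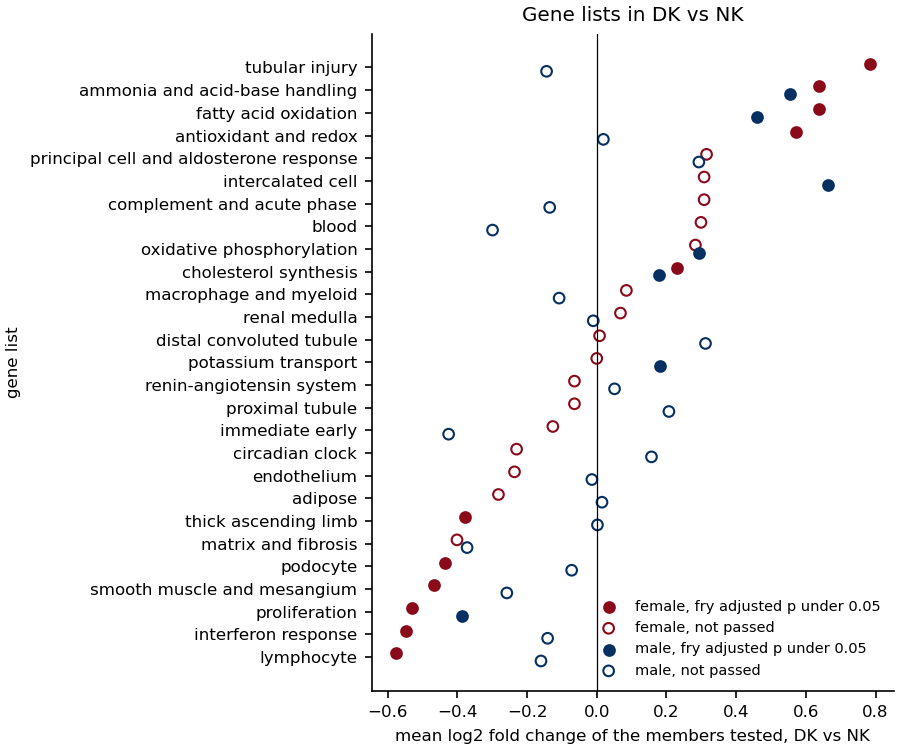
Mean log2 fold change of the tested members of 27 gene lists in DK vs NK for females and males; filled points passed a fry adjusted p of 0.05. The ammonia list has a mean of 0.64 in females and 0.56 in males, and the tubular injury list 0.78 in females and -0.14 in males.

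In males, the same question gave fewer genes. Slc38a3 rose from 53.9 ± 29.3 to 174 ± 93.8 FPKM in DK (SD, n = 6), a log2 change of 1.70 (SE 0.37, limma adjusted p = 0.00641). Abcb11 rose by 2.87, Fam25a by 3.52, Cyp27b1 by 2.51, the xenobiotic hydroxylase Cyp1a1 by 2.38, Rup2 by 1.99 and Tmed6, a member of the secretory cargo receptor family, by 1.74. The ubiquitin ligase Rnf183 fell by 1.26, Wdr86 by 1.18, the prothrombin gene F2 by 1.11, the matrix cross-linking oxidase Loxl2 by 1.0, the protease Adamts4 by 0.95 and the synaptotagmin Syt13 by 0.93. The mitotic genes Plk1 and Prc1 fell by 1.07 and 0.93. In 13 of the 20 genes with the largest changes every DK library lay outside the NK range. Over all tested genes 541 did so, where chance gives 0.216%. With the number series as a covariate, 13 of the 29 results named for male DK vs NK lost their call.

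Others of the 20 genes with the largest changes in males were Rbp4 at 2.10, Klk1c10 at 1.91, Ppp1r1b at -1.48 and Hmox1 at -2.42, and each lost its call without male NK replicate 2. Single libraries ended the call of Klk1c10 in 5 of 12 fits (adjusted p up to 0.0813), of Rbp4 in 8 (up to 0.109), of Ppp1r1b in 8 (up to 0.102) and of Hmox1, the heme oxygenase, in 11 (up to 0.123).

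Of the lists, ammonia and acid-base handling had 9 members up and 11 not passed in male DK vs NK, and 12 up adjusted over the list alone (fry adjusted p = 0.000593; adjusted p = 0.117 with an estimated correlation). Pck1 rose by 1.53, Glud1 by 1.04, the ammonia transporter Rhbg by 0.97 and Rhcg by 0.76. Intercalated cell genes had 11 up and 6 not passed, or 15 up over the list alone (adjusted p = 0.00191; adjusted p = 0.149 with an estimated correlation), Atp6v1g3, a proton pump subunit, at 1.01. Fatty acid oxidation had 13 up and 13 not passed, or 22 up over the list alone (adjusted p = 0.000843; adjusted p = 0.117 with an estimated correlation). Oxidative phosphorylation had 4 up of 36, or 19 over the list alone (adjusted p = 0.0385; adjusted p = 0.395 with an estimated correlation). Cholesterol synthesis had 1 up of 23, Fdft1 at 0.58, or 2 over the list alone (adjusted p = 0.00918; adjusted p = 0.229 with an estimated correlation). Potassium transport had 3 up of 19, or 6 up and 1 down over the list alone (adjusted p = 0.0209; adjusted p = 0.359 with an estimated correlation). Proliferation genes had 9 down and 15 not passed, or 14 down and 2 up over the list alone (adjusted p = 0.00203; adjusted p = 0.153 with an estimated correlation), with Mki67 and Top2a both at -0.74 and the cyclin Ccnb1 at -0.80. The remaining 20 lists did not pass, among them tubular injury with 1 up and 1 down of 24, or 1 and 2 over the list alone (adjusted p = 0.482), lymphocyte with 0 of 17 by either count (adjusted p = 0.137) and podocyte with 1 down of 13 by either count (adjusted p = 0.626). Of the 24 transport and injury genes, 6 rose, 0 fell and 18 did not pass, Lcn2 at 0.06 (adjusted p = 0.951).

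The male total by limma was 680 genes, 416 higher and 264 lower, and it moved with single libraries: 294 without DK replicate 2, 364 without DK 4, 424 without DK 5, 400 without DK 6, 398 without NK replicate 1, 335 without NK 2 and 440 without NK 3. Of the male DK sample numbers 5 lie in the 200s and 1 in the 300s, against 6 in the 300s for NK, so a comparison within the 300s rests on 1 DK library; with that library taken to vary like the other groups 55 genes passed, 41 of them among the 680. With the series as a covariate 87 genes passed, 78 of them among the 680, the median size of the 680 changes going from 0.52 to 0.50 and their median SE from 0.13 to 0.19, and the ammonia (adjusted p = 0.0231), fatty acid oxidation (0.00351) and proliferation (0.0231) lists passed. With library sums 245 genes were higher and 1038 lower, and the cholesterol synthesis (adjusted p = 0.397), oxidative phosphorylation (0.0969) and potassium transport (0.388) lists lost their calls; with the replicate number as a block oxidative phosphorylation did (0.0535).

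Whether the sexes differed in their response to potassium deficiency was tested by the interaction of sex and diet, males minus females. Rbp4 rose less in males, with a difference of -4.57 on the log2 scale (SE 0.85, limma adjusted p = 0.000527); its male mean was 21.1 ± 23.1 FPKM in DK (SD, n = 6) and 2.72 ± 1.25 in NK. Sds differed by -3.88 and Gstm1 by -3.68. Tat, at -3.89, had 2 reads over the 6 male NK libraries, so its male change is set by the pseudocount and a smaller rise in males cannot be read from it. Oacyl differed by 3.37, Slc16a14 by 2.95, Fsd1l by 2.81 and Akr1b7 by 3.56, which fell in females. Oacyl stood at 0.59 to 1.297 FPKM in male NK, near the pseudocount of 0.5, so a fall of 4.24 as in females could not appear. Akr1b7 stood at 0.0235 ± 0.0258 FPKM in male DK and at 0.00732 ± 0.0179 in male NK, so that its difference reflects the female change alone. Hnmt, which inactivates histamine, differed by 2.83. Hmox1 differed by -4.40: it stood at 1.99 in females, where its call ended without DK replicate 2, 3 or 6 or NK replicate 5 (adjusted p = 0.0541 to 0.0832), and stood at 111.5 ± 161 FPKM in male NK, where a single library, replicate 5, reached 439.

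The change of tubular injury genes in DK vs NK differed between the sexes, with 9 members lower, 1 higher and 14 not passed in males relative to females, or 17 and 2 adjusted over the list alone (fry adjusted p = 0.0252; adjusted p = 0.644 with an estimated correlation). The list was higher in males on NK (0.000829; adjusted p = 0.255 with an estimated correlation) and did not pass between the sexes on DK (0.981). Lcn2 differed by -2.14, Gdf15 by -1.97, the cell cycle inhibitor Cdkn1a by -1.60 and clusterin, Clu, by -1.47. Antioxidant genes had 8 lower and 2 higher of 25, or 9 and 2 over the list alone (adjusted p = 0.0252; adjusted p = 0.644 with an estimated correlation), with Gstp1 at -1.92 and Gclc at 2.22. Lymphocyte genes had 2 higher, 1 lower and 14 not passed, or 4 and 1 over the list alone (adjusted p = 0.0252; adjusted p = 0.644 with an estimated correlation), Il2rb at 0.70. Interferon response genes had 8 higher of 23, or 8 higher and 1 lower over the list alone (adjusted p = 0.0684), Mx1 at 1.56 and Irf7 at 1.2, and clock genes 6 higher and 2 lower of 17, or 9 and 3 (adjusted p = 0.0966), Arntl at -2.33, Dbp at 1.96 and Ciart at 2.64. The ammonia list had 3 higher and 3 lower of 20, or 6 and 5 over the list alone, with a median of 0.08, a mean of -0.08 and an upward direction (adjusted p = 0.932), and fatty acid oxidation 1 lower of 26 by either count (adjusted p = 0.53).

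The interaction called 1420 genes by limma, 687 positive and 733 negative, and the change was larger in size in females for 1357 and in males for 63. Of the sample numbers, 5 of 6 in male DK and 4 of 6 in female NK lie in the 200s and the others in the 300s; with this series as a covariate 57 genes passed, 54 of them among the 1420; the median size of the 1420 differences went from 0.74 to 0.60 and their median SE from 0.19 to 0.30, and none of the 3 lists passed. Of the 22 genes named for this difference, Fsd1l and Il2rb still passed. Tat and Akr1b7, whose male changes lie near the floor, and Oacyl, whose male fall is limited by the pseudocount, passed as well. The difference of Rbp4 went to -1.49 (limma adjusted p = 0.748) and that of Dbp to 0.68 (adjusted p = 0.788). Within the 300s, with 1 male DK library taken to vary like the other groups, 32 genes passed, 29 of them among the 1420. With library sums 1384 genes passed, 821 positive and 563 negative, so that the balance of signs depends on the scaling, and the lymphocyte and tubular injury lists did not (both adjusted p = 0.0587); with the replicate number as a block tubular injury did not (0.0541). Across all 14264 genes the male and female changes had a Pearson r of 0.466, or 0.294 with the number series as a covariate, and a Spearman rho of 0.494 (genes are not independent replicates), with a slope of 0.252 of male on female. Genes called higher in both sexes numbered 315, where chance gives 81.8, and lower in both 194, where chance gives 51.5; 14 were called in opposite directions.

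**Figure D5:**
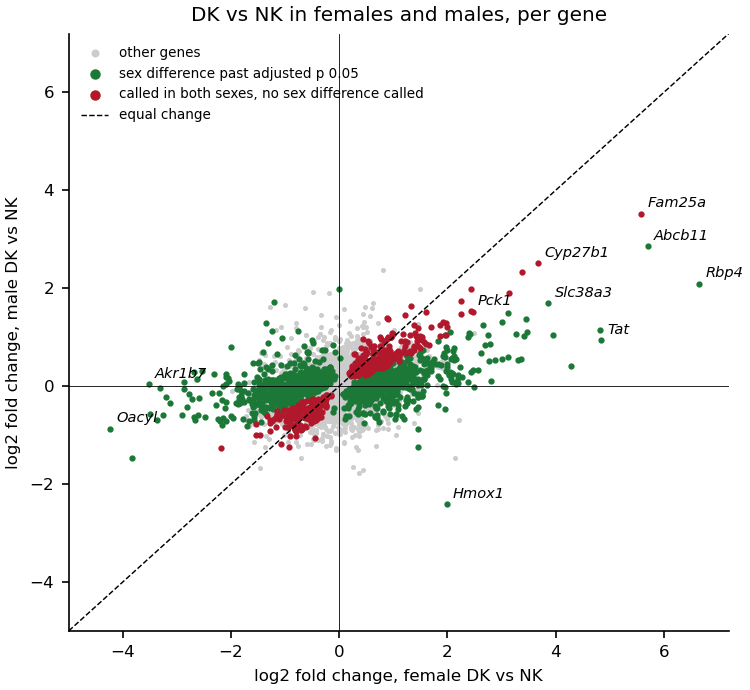
Log2 fold change in DK vs NK of each tested gene, females on the x axis and males on the y axis; green points passed the test of a sex difference and the dashed line marks equal change. Of the 1420 green points, 1357 have the larger change in females.

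High potassium was compared with normal potassium to ask what supplementation changes under high salt. In females no gene passed by limma (0 higher, 0 lower; 381 genes at an unadjusted p under 0.05; smallest adjusted p = 0.621), and voom on recovered reads also gave 0. The 24 transport and injury genes lay between -0.12 for Wnk4 and 0.86 for Atp12a, a proton potassium pump, at 3.05 ± 1.52 FPKM in HK (SD, n = 5) and 1.66 ± 1.72 in NK (n = 6). Slc12a3 stood at -0.02, Scnn1a at 0.35 and Pck1 at 0.15, each with an adjusted p of 1. None of the 27 lists passed (smallest fry adjusted p = 0.883), among them tubular injury with a mean of 0.22.

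In males 0 genes passed by limma in HK vs NK (1076 at an unadjusted p under 0.05; smallest adjusted p = 0.413), and 0 by voom. Injury genes had the lowest values of those examined: Havcr1 stood at 40.8 ± 32.4 FPKM in HK and 79 ± 25 in NK (SD, n = 6), a log2 change of -1.12 (adjusted p = 0.604). Lcn2 stood at -0.89 and Spp1, osteopontin, at -0.75. HK replicate 5 stood far above its group, with Havcr1 at 107, Lcn2 at 113 and Spp1 at 6648 FPKM. The other HK libraries lay at 24.9 to 30.4, 25.2 to 36.6 and 1768 to 2443. The tubular injury list had a mean of -0.50 and did not pass (fry adjusted p = 0.143), though 8 members were lower when adjusted over the list alone; 4 podocyte genes were higher by that count. Weights per library, which gave male HK replicate 5 a weight of 0.51 and male HK replicate 4 a weight of 2.82, called 387 genes. Under these weights Havcr1, Lcn2 and Spp1 were each called lower in HK. Leaving out HK replicate 5 called 5, and leaving out male NK replicate 3 called 1.

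The sex difference in HK vs NK gave 0 genes by limma (805 at an unadjusted p under 0.05; smallest adjusted p = 0.709) and 0 by voom, and no list passed (smallest fry adjusted p = 0.21), though 7 tubular injury genes were lower and 9 clock genes higher and 2 lower when adjusted over the list alone. Female and male changes had a Pearson r of -0.054 across genes. With 5 libraries of female HK and 6 of each other group, simulated 2-fold changes were recovered in 82% of genes for the female and 83% for the male HK vs NK comparison, and 1.5-fold changes in 53% and 52%. The sex difference itself was not simulated. Its median SE was 0.181, against 0.131 in females and 0.125 in males, so smaller shares would be recovered there.

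Both DK and HK were compared with the same NK libraries, and such comparisons correlate even when nothing changes. Across genes the female DK and HK changes had an r of 0.223, against a mean of 0.465 for simulated unchanged groups, and a covariance of 0.0241 against 0.0211. With the NK libraries split between the comparisons r was 0.02. For males r was 0.385 against 0.491 simulated, the covariance was 0.0245 against 0.0212 and the split gave 0.079.

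The ends of potassium intake, DK against HK, were compared within each sex. In females Rbp4 stood at 2.02 ± 0.893 FPKM in HK (SD, n = 5) and was higher in DK by 7.50 on the log2 scale (SE 0.63, limma adjusted p = 1.15e-10). Slc38a3 was higher by 3.56, Cyp27b1 by 3.88, the vitamin D dependent calcium binding protein S100g by 3.73, Pck1 by 2.29, Glud1 by 1.94 and Gpt by 1.97. Kcne1, a potassium channel subunit, was lower, at -2.68, Gatm at -2.59, the lipid enzyme Tmem86a at -2.56 and Kcnj10 at -1.46. The subunit Scnn1b, which did not pass against NK, was at -0.59 (adjusted p = 0.00729) and Scnn1g at -0.74. Ammonia genes had 10 up and 3 down of 20, or 11 and 3 adjusted over the list alone (fry adjusted p = 0.000445; adjusted p = 0.767 with an estimated correlation). Oxidative phosphorylation had 17 up of 36, or 26 over the list alone (adjusted p = 0.0204; adjusted p = 0.788 with an estimated correlation). Matrix and fibrosis genes had 12 down and 4 up of 29, or 15 and 4 over the list alone (adjusted p = 0.0356; adjusted p = 0.788 with an estimated correlation). In all 13 lists passed, and limma called 5188 genes, 2656 higher and 2532 lower; all 11 libraries belong to the 300s. With library sums 1201 were higher and 5252 lower, and 9 of the 13 lists stayed called, oxidative phosphorylation not among them (fry adjusted p = 0.377). The clock (0.0232), endothelium (0.0121), potassium transport (0.017) and renin-angiotensin (0.0211) lists passed with library sums only. Median-ratio scaling ended the calls of tubular injury (0.0506) and cholesterol synthesis (0.0574).

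In males on DK against HK, Slc38a3 was higher by 1.68 (SE 0.37, limma adjusted p = 0.0076), Pck1 by 1.32, Glud1 by 0.94, Abcb11 by 2.81, Cyp27b1 by 2.54, Gp2, a membrane protein related to uromodulin, by 1.98 and Gstm1 by 1.90. F2 was at -1.49 and the lipid transporter family member Spns3 at -1.21. Ammonia genes had 6 up of 20, or 10 up and 1 down adjusted over the list alone (fry adjusted p = 0.0179; adjusted p = 0.4 with an estimated correlation). Fatty acid oxidation had 10 up of 26, or 18 over the list alone, and cholesterol synthesis 2 up of 23, or 9 (both adjusted p = 0.00215; adjusted p = 0.196 with an estimated correlation). Podocyte genes had 2 down of 13, or 9 over the list alone (adjusted p = 0.0328; adjusted p = 0.4 with an estimated correlation). Limma called 616 genes, 385 higher and 231 lower, but 1046 without DK replicate 1, 279 without DK 2, 252 without DK 4, 304 without DK 5, 319 without DK 6, 403 without HK replicate 2, 385 without HK 3, 334 without HK 4 and 268 without HK 6. With the number series as a covariate 129 passed, 111 of them among the 616, and of the 4 lists fatty acid oxidation alone passed (adjusted p = 0.00699). Within the 300s, with 1 DK library, 97 passed, 69 of them among the 616. With library sums 210 were higher and 484 lower.

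The sex difference in DK vs HK was called for 777 genes by limma, 340 positive and 437 negative, of which 751 had the larger change in females; 350 passed with the number series as a covariate, 324 of them among the 777, and 38 within the 300s with 1 male DK library, 35 of them shared. With library sums 766 were positive and 294 negative. Rbp4 differed by -5.86 (SE 0.87, adjusted p = 6.26e-05), Tat by -4.31, Sds by -3.27, S100g by -3.22 and Abcb11 by -2.73. Akr1b7, with 3 and 2 reads over the male DK and HK groups, differed by 3.90, Oacyl by 3.08, Nkx1-2 by 2.83, Fsd1l by 2.75 and Rup2 by 2.63. Oacyl stood at 0.5606 to 3.559 FPKM in male HK, so the female fall of 4.51 could not appear there either. Rup2 had no read in female DK and HK, where 3 reads per library would be at most 0.371 FPKM, and its 3.64 FPKM in male DK were at least 9-fold higher. No list passed; antioxidant, interferon response, lymphocyte and proliferation genes each had a fry adjusted p of 0.0502, and these and cholesterol synthesis passed with library sums (adjusted p = 0.0307 to 0.0423).

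Males and females were compared on each diet to describe the sex difference itself. On NK, the dehydrogenase family member Dhrs7l1 was higher in males, 100.3 ± 57.9 against 0.392 ± 0.215 FPKM (SD, n = 6), a log2 difference of 6.66 (SE 0.32, limma adjusted p = 8.2e-17). The organic anion transporters Slco1a1 and Slc22a22 were higher by 5.68 (with 16 reads over the 6 female libraries for Slco1a1) and 5.20 and the reductase Akr1c12l1 by 3.90. Females had more Akr1b7, with 57.06 FPKM on average against 1 read over the 6 male libraries, Armc3 at -4.41, the organic anion transporter Slc22a7 at -4.17 and the amino acid transporter Slc7a12 at -3.95. Of the sex-linked transcripts, Eif2s3y had 3 reads over the 6 female NK libraries and XIST_intron, a piece of the X-inactivating RNA, 1 read over the 6 male ones.

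On NK 15 of the 27 lists differed between the sexes by fry. Higher in males on NK were matrix and fibrosis, 21 of 29 or 23 adjusted over the list alone (fry adjusted p = 0.00107), tubular injury, 16 of 24 or 20 (0.000829), macrophage and myeloid, 17 of 25 or 20 (0.000829), proliferation, 19 of 24 or 21 (2.04e-05), complement and acute phase, 9 of 20 or 12 (0.00107), and lymphocyte, 5 of 17 or 5 (0.00171); each had adjusted p = 0.255 with an estimated correlation. Examples were the collagen Col1a2 at 0.99, Havcr1 at 1.69, the injury-induced factor Sox9 at 2.46, the macrophage receptor Csf1r at 0.70, Ccnb1 at 0.93 and complement C4b at 1.64. Interferon response had 5 higher of 23, or 5 over the list alone (adjusted p = 0.0116; adjusted p = 0.332 with an estimated correlation). Lower in males were intercalated cell, 13 of 17 or 17 over the list alone (0.00107), and distal convoluted tubule, 8 of 14 or 9 (0.000829), both with adjusted p = 0.255 with an estimated correlation. Egf, a growth factor of the distal tubule, was at -1.40, the anion exchanger Slc4a1 at -0.90 and Rhcg at -0.82. Potassium transport had 5 lower and 1 higher of 19, or 7 and 1 over the list alone (0.00114; adjusted p = 0.286 with an estimated correlation). Ammonia had 6 lower of 20, or 6 (0.00582), and principal cell 5 of 17, or 9 lower and 1 higher (0.00445), both with adjusted p = 0.332 with an estimated correlation. Oxidative phosphorylation had 18 lower of 36, or 29 (0.01), podocyte 6 of 13, or 7 (0.0116), and the renin-angiotensin list 4 lower and 1 higher of 12, or 6 and 1 (0.0121), each with adjusted p = 0.383 with an estimated correlation. Angiotensinogen, Agt, was higher by 2.37.

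On NK limma called 3001 genes, 1400 higher in males and 1601 lower. The 2 female NK libraries of the 300s against the 6 male ones gave 784, of which 736 were among the 3001, and the number series as a covariate gave 1285, of which 1213 were shared; the covariate ended the calls of the interferon response (adjusted p = 0.0538), oxidative phosphorylation (0.0692) and renin-angiotensin (0.0872) lists. With library sums 2750 genes were higher in males and 879 lower, and the ammonia (adjusted p = 0.0525), podocyte (0.126), potassium transport (0.067), principal cell (0.0675) and renin-angiotensin (0.714) lists lost their calls.

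On DK, 4906 genes differed between the sexes, 2294 higher in males and 2612 lower. Beyond the genes above, Tat was at -5.37, Sds at -5.21, Rbp4 at -5.08 and the alcohol dehydrogenase Adh6 at -3.22 (SE 0.20, limma adjusted p = 3.93e-14), from 68.6 ± 17.8 FPKM in males and 646 ± 194 in females (SD, n = 6). Eif2s3y had no read in female DK and was at least 310-fold higher in males by a floor of 3 reads per library, and XIST_intron at least 182-fold lower. Lymphocyte genes had 15 higher in males of 17, or 16 higher and 1 lower adjusted over the list alone (fry adjusted p = 4.67e-08; adjusted p = 0.135 with an estimated correlation). Interferon response had 19 higher and 1 lower of 23, the same over the list alone, and proliferation 20 and 1 of 24, the same over the list alone (6.62e-07 and 3.09e-07; both adjusted p = 0.202 with an estimated correlation). In all 13 lists passed. With the number series as a covariate 2287 genes passed, 2199 of them among the 4906, and 7 lists. Within the 300s, with 1 male DK library, 428 passed, 418 of them shared. With library sums 4550 were higher in males and 1258 lower, and 7 of the 13 lists stayed called. The cholesterol synthesis (fry adjusted p = 0.00287), clock (0.00141) and complement (0.0362) lists, not called before, passed. Median-ratio scaling ended the call of oxidative phosphorylation (0.0513).

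On HK, 1415 genes differed, 573 higher in males and 842 lower. Slc51b, a subunit of the bile acid and steroid exporter, was higher by 4.26 (SE 0.30, limma adjusted p = 1.17e-12), at 73.35 ± 17.4 FPKM in males (SD, n = 6) and 3.37 ± 1.01 in females (n = 5), and Angpt2, which acts on vessels, was at -3.88. XIST_intron had no read in male HK and was at least 146-fold lower than in females. Leaving out female HK replicate 5 left 846 genes. Lymphocyte genes had 4 higher of 17, or 8 adjusted over the list alone (fry adjusted p = 0.0107; adjusted p = 0.575 with an estimated correlation), and fatty acid oxidation 8 lower and 1 higher of 26, or 13 and 1 over the list alone (adjusted p = 0.0405; adjusted p = 0.575 with an estimated correlation; 0.0723 with library sums).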

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

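The tests of other splits of the libraries were planned before the results were seen, except that subtracting the effects of sex and diet before the splits of the 3 sex differences was chosen after; the tests of the 3 patterns weighed at the end were chosen after. Values far from the rest of their group were searched for the named genes and for reads, mitochondrial share and share of the top 10 genes, by the gap to the nearest other library over the range of the group. Of 335 groups of gene values 44 had such a value (13.1%), and of 18 groups of library measures 4 did. Chance gives about 1 in 20 only for normally distributed values, which was not tested for FPKM. Groups in which a single library had a read also counted, as for Tat in male NK. The 13.1% is thus no measure of an excess. The most came from female DK replicate 1 with 8, male HK replicate 5 with 6 and female NK replicate 6 with 5.

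In female DK replicate 1, Gatm stood at 280 FPKM, Cldn16 at 11.5, Itga8 at 2.73, Col1a1 at 17, Col6a3 at 3.69, Ace at 11.9 and Kcnj1 at 153, and the top 10 genes held 13.87% of the reads. Replicate 3 had Npnt at 10.1 and Clu at 929, replicate 5 had Nr1d1 at 34.8 and 28.66 M reads, and replicate 6 had Hsd11b2 at 196. In female NK, replicate 6 had Slc38a3 at 105, Arntl at 3.17, Ace at 4.01, Atp12a at 5.11 and Eif2s3y at 0.113; replicate 4 had Rbp4 at 31.8 and Gstp1 at 325, replicate 5 Dio1 at 164 and Kcnj1 at 118, and replicate 2 Gdf15 at 144 and Itga8 at 1.32. In female HK, replicate 5 had Akr1b7 at 145. In male DK, replicate 1 had Ppp1r1b at 28.3 and Oacyl at 2.01, replicate 2 Top2a at 2.67 and Ccnb1 at 4.83, replicate 4 Spns3 at 1.28 and replicate 5 Cyp27b1 at 21.4. In male NK, replicate 5 had Hmox1 at 439, replicate 2 Gstm1 at 36.0 and Armc3 at 0.856, replicate 3 Akr1b7 at 0.0439, replicate 4 Fam25a at 3.29, and replicate 6 Tat at 0.0551, XIST_intron at 0.937 and C4b at 54.5. In male HK, replicate 5 had Havcr1 at 107, Lcn2 at 113, Spp1 at 6648, Gp2 at 2.17, Gstm1 at 62.4 and a top 10 share of 10.86%, replicate 3 Akr1b7 at 0.0938, replicate 4 20.91 M reads and replicate 6 Abcb11 at 1.41.

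The sexes differed in DK vs NK by the interaction test for 1420 genes and for the antioxidant, lymphocyte and tubular injury lists (each adjusted p = 0.0252; 0.644 with an estimated correlation). With the number series as a covariate 57 genes and none of these lists passed. Negative differences, males minus females, were found for Rbp4 (-4.57), Hmox1 (-4.40), Tat (-3.89), Sds (-3.88), Gstm1 (-3.68), Cldn24 (-2.90), Abcb11 (-2.83), Cldn22 (-2.35), Arntl (-2.33), Slc38a3 (-2.17), Lcn2 (-2.14), Gdf15 (-1.97), Gstp1 (-1.92), Dhcr7 (-1.80), Gpnmb (-1.67), Cdkn1a (-1.60), Gpt (-1.59), Cyp4a2 (-1.51), Clu (-1.47), Ace (-1.32), Krt8 (-1.26) and Glud1 (-0.92). The male changes of Tat and Akr1b7 lie near the floor, and the male fall of Oacyl is limited by the pseudocount. Rup2 had no read in female DK and a female change of 0.0, so its difference reflects the male change alone. Positive ones were found for Akr1b7 (3.56), Oacyl (3.37), Slc16a14 (2.95), Hnmt (2.83), Fsd1l (2.81), Nkx1-2 (2.79), Gatm (2.68), Dio1 (2.65), Ciart (2.64), Hao2 (2.61), Rdh16 (2.45), Cryga (2.39), Gclc (2.22), Rup2 (1.99), Dbp (1.96), Mx1 (1.56), Col6a3 (1.49), Nr1d1 (1.43), Col1a1 (1.38), Kcnj10 (1.21), Irf7 (1.2), Cldn16 (1.01), Scnn1g (0.98), Rgs5 (0.96), Cldn10 (0.90), Npnt (0.87), Top2a (0.71), Ptprc (0.70), Il2rb (0.70), Agtr1a (0.60) and Fdft1 (0.56).

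In DK vs HK the sexes differed for 777 genes, or 350 with the number series as a covariate. Among those named were Rbp4 (-5.86), Tat (-4.31), Sds (-3.27), S100g (-3.22), Abcb11 (-2.73), Gstm1 (-2.55), Slc38a3 (-1.88), Gpt (-1.41), F2 (-1.11), Glud1 (-1.0), Akr1b7 (3.90), Oacyl (3.08), Nkx1-2 (2.83), Fsd1l (2.75), Rup2 (2.63), Kcne1 (1.99), Tmem86a (1.55) and Scnn1g (0.79).

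Each number of genes was set against 100 splits of the libraries of its groups, the real one included. Only the real split was as large for female DK vs NK (5584, highest other 4922), male DK vs NK (680, other 164) and female DK vs HK (5188, other 4173). The same held for males against females on NK (3001, other 796), DK (4906, other 4865) and HK (1415, other 606). Each highest other was the real grouping or its mirror with 1 library of each group exchanged, or 1 moved on HK. The 4865 genes came from the mirror of the real sexes with female DK replicate 1 and male DK replicate 6 exchanged. The median over the other splits was 0 in each of these comparisons. For male DK vs HK 2 of 100 splits were as large. A grouping with DK replicate 1 and HK replicate 5 exchanged, up to the mirror, gave 953 genes against the real 616. For the sex differences the diets were shuffled within each sex after the effects of sex and diet common to the groups were subtracted. There, only the real split was as large in DK vs NK (1420, other 294) and DK vs HK (777, other 1). These counts argue against chance, but 100 splits cannot exclude it, least of all for male DK vs HK. For the 0 genes of female HK vs NK (highest other 24), male HK vs NK (493) and the sex difference in HK vs NK (1), 100 of 100 splits gave as many. No split can give fewer than 0, so this outcome was fixed in advance and carries no information. The 493 genes came from the male diet grouping, up to the mirror, with HK replicate 5 and NK replicate 4 exchanged. Weights per library called 387 genes in male HK vs NK and leaving out HK replicate 5 called 5, so that library alone does not account for the 387. The weights also act on other libraries, with 2.82 for male HK replicate 4 and 0.18 for female DK replicate 3. Whether a diet difference was missed stays open.

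The smaller response of males to the DK diet was weighed first. A shift added to every library of the 200s was examined in female NK. There the 4 libraries of the 200s minus the 2 of the 300s lay at -0.006 (SE 0.104) on the axis of genes called in males. Male minus female DK lay at -0.49 (exact permutation p = 0.00649). This argues against a shift as large as the whole -0.49. With 4 and 2 libraries, a shift that accounts for a part of the -0.49 cannot be excluded. The authors' scaling was argued against: with library sums in its place the sex difference moved by 0.045 over all genes, against a median size of 0.74 for the 1420 called, and 1384 genes passed. Whether male DK animals of the 200s responded less than those of the 300s cannot be told apart from sex, because 1 male DK library belongs to the 300s (exact permutation p = 0.5). With the series as a covariate the sex difference in DK vs NK on the axis of male-called genes went from -0.46 (SE 0.137) to -0.298 (SE 0.219). A cohort effect and a sex difference both may contribute.

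The circadian clock list passed neither in female DK vs NK (fry adjusted p = 0.0741; 0.864 with the number series) nor in males (0.365) nor in the sex difference (0.0966). A score of 7 clock genes chosen after their values were seen, the mean of Dbp, Nr1d1, Per3 and Ciart minus that of Arntl, Npas2 and Nfil3, changed by -2.103 in female and 1.251 in male DK vs NK. Collection at times of day that followed the sample number may explain this, since scores of neighbouring numbers were closer than when shuffled within groups (sum of steps 27.91 against 36.8 with an SD of 3.91; permutation p = 0.0125, 100000 shuffles). The shuffles mixed the 200s and 300s within a group, so any difference between the series would also bring neighbours closer. The score of the 200s minus the 300s was 0.935 in female NK and 1.661 in male DK, which has 1 library of the 300s. The test thus cannot tell time of day from another difference between the series. Collection times are not in the labels. A sex difference in these genes under potassium deficiency stays open and was not tested apart from time of day or series.

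The lymphocyte, podocyte and smooth muscle lists were lower in female DK. With library sums in place of the authors' scaling all genes moved by -0.173, so that scaling had raised female DK values against NK. The 3 lists stayed called lower with library sums (fry adjusted p = 8.02e-06, 3.34e-05 and 0.00151). They also stayed lower after median-ratio scaling (8.03e-06, 0.000969 and 0.00408). Library sums lowered the female DK changes as a whole, so lists already lower were set to stay lower. Median-ratio scaling moved all genes by only -0.009. Neither setting can therefore decide whether scaling is the source of the 3 lower lists. The values show only that the authors' scaling did not lower them relative to library sums. A smaller share of every cell type other than tubule cannot be told apart from an effect of the diet on each cell type. Against it, the macrophage minus lymphocyte mean per library was higher by 0.662 in DK (exact permutation p = 0.00216, the smallest these permutations can give), with the macrophage mean at 0.085 (p = 0.403), and the median of macrophage genes lay above that of lymphocyte genes by 0.489. The lymphocyte mean alone changed by -0.577 (exact permutation p = 0.00216). The p of the difference thus restates the fall by which this list was picked and is no separate evidence. What keeps a smaller share of these cell types open is that macrophage genes went both ways, 10 above 0 and 15 below, with an SD of 0.774, and that endothelium genes had 4 called lower and 0 higher.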

How the results depend on the processing

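The alternatives without the 3 libraries of lowest weight (female DK replicates 1 and 3 and female NK replicate 2), of the 300s with 1 male DK library and with library sums in place of the authors' scaling were chosen after seeing the data; all other alternatives were planned. Under both other pseudocounts, both filters, median-ratio scaling, quantile normalization, the fit of the contrast's groups alone where genes were called, the replicate block and voom, the number of genes of each of the 12 comparisons stayed within 1.5 times the value reported. The replicate numbers did not pair the libraries: residual correlations of libraries sharing a number averaged -0.011 over 85 pairs, and the block gave 5381 genes for female DK vs NK and 576 for male DK vs NK. With the number series as a covariate the counts were 3701 for female DK vs NK, 87 for male DK vs NK, 129 for male DK vs HK, 57 and 350 for the sex differences in DK vs NK and DK vs HK, and 1285 and 2287 for males against females on NK and DK. The covariate raises the standard errors where the series follows the groups: for the 680 male genes the median SE went from 0.13 to 0.19 with a median size of 0.52 and then 0.50, whereas for the 1420 genes of the sex difference the size also fell, from 0.74 to 0.60. Libraries of the 300s alone gave 3471 for female DK vs NK, 784 for males against females on NK and 1 for female HK vs NK (Nfs1, at -4 and adjusted p = 0.0112), with fewer libraries. Male DK has 1 such library; taken to vary like the other groups, it gave 55 for male DK vs NK, 97 for male DK vs HK, 32 and 38 for the sex differences in DK vs NK and DK vs HK, and 428 for males against females on DK. The fit of female HK and NK alone gave 1 gene (SNORA41, at -1.93). Weights per library gave 1673 for male DK vs NK, 387 for male HK vs NK, 1923 for male DK vs HK, 2218, 6 and 1483 for the sex differences in DK vs NK, HK vs NK and DK vs HK, and 2445 for males against females on HK. Without the 3 libraries of lowest weight the counts were 1387 for male DK vs NK, 1487 for male DK vs HK, 1314 for the sex difference in DK vs HK and 2150 for males against females on HK; the 3 libraries are female DK and NK, so the 2 counts of male libraries moved through the shared variance alone. Library sums gave 1283 for male DK vs NK, and the other 11 counts stayed within 1.5 times. Nfs1 and SNORA41 were named after their values were seen.

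Leaving out single libraries gave 4950 to 6113 genes for female DK vs NK, 294 (without male DK replicate 2) to 914 (without male DK replicate 1) for male DK vs NK, 0 to 0 for female HK vs NK, 0 to 5 for male HK vs NK (5 without male HK replicate 5: Anxa2, Kdm1a, Nudt21, Parp9 and Snx4; 1 without male NK replicate 3: AC125982.2; named after their values were seen), 4440 to 5822 for female DK vs HK and 252 to 1046 for male DK vs HK. The sex differences ranged from 1083 to 1782 in DK vs NK, 0 to 0 in HK vs NK and 598 to 1110 in DK vs HK, and males against females from 2322 to 3092 on NK, 4085 to 5590 on DK and 846 (without female HK replicate 5) to 1504 on HK. Other single libraries that moved a count more than 1.5 times stand in the report beside that count.

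Camera with an estimated correlation called 0 lists in female DK vs NK, male DK vs NK, both DK vs HK, the sex difference in DK vs NK and males against females on each diet, where fry called 11, 7, 13, 4, 3, 15, 13 and 7. With a preset correlation it called 15 for male DK vs NK, 9 for female and 18 for male HK vs NK, 8 for male DK vs HK, 7, 15 and 5 for the sex differences in DK vs NK, HK vs NK and DK vs HK, and 14 for males against females on HK. It also called 11 for female DK vs NK, of which 9 were shared with fry, and 12 for female DK vs HK, of which 11 were shared. For males against females it called 18 on NK, of which 14 were shared, and 12 on DK, of which 12 were shared. Fry with the series gave 3 for male DK vs NK, 1 for male DK vs HK, 0 for the sex difference in DK vs NK and 7 for males against females on DK. With library sums fry gave 4 for male DK vs NK and 1 and 5 for the sex differences in DK vs NK and DK vs HK, and of 183 named gene results 182 kept their side of the threshold. The replicate block also ended the calls of tubular injury in female DK vs HK (0.0648), oxidative phosphorylation between the sexes on DK (0.0587), and interferon response (0.0524) and principal cell (0.0628) on HK, beside those given in the report. The correlation of the sexes in DK vs NK was 0.294 with the series. Kcnj16 in female DK vs NK reversed under quantile normalization, from 0.01 to -0.376. The cause of these differences was not tested except where stated. At a median of 14.98 M reads, genes under the filter were left untested.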

Other observations

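The values here belong to no single comparison of the report, and no tests were run on them. Mt-co1 took 4.19% and Gpx3 3.97% of the reads in female DK, where Pck1 took 1.95%. Residual correlations between libraries that share a replicate number ranged from -0.273 to 0.213, with 13 of 85 pairs above 0.1, and 10 of 35 libraries were closest to a library with their own number.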
